A study of Mus musculus with 13 samples.

How the data were processed

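RNA-seq was analysed for 6 mouse Th17 cell libraries, 3 labelled wild type for Chaf1b (WT) and 3 labelled as carrying a conditional Chaf1b knockout (KO). Groups and replicate numbers were taken from the sample titles and genotype labels. The labels call the 3 libraries of each genotype biological replicates and do not say whether each came from a separate animal, so the p-values measure the spread between these libraries. The other 7 of 13 samples (H3K4me3 and Chaf1b ChIP-seq, ATAC-seq and CUT&Tag) were not analysed here. RNA was extracted with TRIzol and libraries were made with a TruSeq kit, per the labels' protocols.

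The deposited table holds raw counts per gene, which the authors made with featureCounts 2.0.1 and the GENCODE vM33 annotation, per the file headers. The file headers record that exons were counted and summed by gene. The commands of 5 libraries set no strand, no counting of multi-mapping reads and no paired-end option; the command of KO replicate 1 is printed without its option names and program version. The aligner version and the genome build are not given in the sources used here. Without strand, reads of a gene cannot be told from those of an antisense neighbour, and overlapping genes or near-identical copies lose or share reads. Low counts were even more often than odd: of counts from 1 to 20, between 65.6% and 67.7% were even, against 48.8% to 50.9% of counts of 1000 or more, the pattern left when both mates of a pair are counted. The depths, floors and sampling noise given per count then rest on fewer fragments than counts. Each of the 6 columns is headed by an alignment file, was matched to its library through the command that names both, and was checked to hold whole numbers. In the record of units kept here the deposited values of 5 columns are entered as counts and those of WT replicate 2 as other; that column holds raw counts like the rest.

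Gene IDs were matched to symbols without their version, which succeeded for 51948 of 56941 IDs (91.2%). Rows without a symbol held between 0.181% and 0.204% of the counts of a library and stayed in the tests under their ID. Where IDs shared a symbol, the ID with the most counts kept it. The GRCm38.p6 RefSeq gene table was used only for which genes neighbour each other, and no coordinates are given. Total counts ran from 35708879 to 45232055 per library, and TMM factors from 0.984 to 1.016. The precision set by these counts depended on level: the median half-width of the 95% interval of a log2 fold change was 1.06 for tested genes under 1 CPM, 0.53 from 1 to 5 CPM, 0.27 from 5 to 20 CPM and 0.15 from 20 CPM. Floors of 3 counts cover counting error only. Every pair of libraries differed by more than sampling noise (chi-square per degree of freedom of at least 4.20 for all pairs, over genes with at least 20 counts in the pair), so all 6 were kept.

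The libraries labelled KO and WT were compared with edgeR 4.0.16 (R 4.3.3), with the default filter on low counts, TMM normalization, a robust quasi-likelihood fit and the quasi-likelihood F-test, and p-values were adjusted by Benjamini and Hochberg over 14681 genes with a threshold of 0.05. The biological coefficient of variation was 9.28%. Fold changes are KO over WT, CPM values use the TMM library sizes, errors of CPM are SD over 3 libraries, and the SE of a log2 fold change was the absolute log2 fold change over the square root of F. Gene lists (30 programme and 13 control lists) were written before the data were examined. The 29 programme lists with at least 5 tested members were tested with camera (limma 3.58.1) at a preset correlation of 0.01, adjusted over the lists; the germline list had 2 tested members and was not tested. The control lists were summed as CPM of the library total and compared with a two-sided exact permutation test, whose smallest p for 3 against 3 libraries is 0.1.

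Genes were named by a rule fixed before the data were examined: Chaf1b and Chaf1a; Il17a, Il17f, Il22, Il21, Csf2, Il23r, Ifng, Tbx21, Foxp3 and Il10 whatever their result; the 10 largest rises and 10 largest falls among genes past the threshold with no overlap of the groups and a mean of at least 5 CPM, leaving out predicted genes and pseudogenes; and for each list past camera or with at least 3 members past the threshold, the 4 called members with the largest change, or the 3 with the highest mean CPM where none passed. Some genes that the rule picks are not reported here. Any list member changed at least 2-fold past the threshold could be named as well. Other members named in the text, to complete a count or to describe a control list, and the genes named in the closing observations outside this rule were chosen after their values were seen.

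The gene test was run on simulated counts drawn from the means, dispersions and library sizes of these 6 libraries, with 14414 genes tested. It recovered 45 of 66 genes changed 1.5-fold (68.2%), 47 of 66 changed 2-fold (71.2%) and 59 of 66 changed 4-fold (89.4%), and 7 of its 158 calls were false (4.43%). On a second such simulation, in which 1 list was shifted, camera called that list and none of the other 28. The simulated genes were drawn independently, so this cannot show how often correlated genes give false list calls. No simulated library was set apart from its group, as WT replicate 1 was in the data. The share of false calls may therefore not hold for the real gene calls. The alternatives tried were DESeq2 size factors and upper-quartile factors in place of TMM, no filter and a filter of at least 5 CPM in 3 libraries, the fit without each library, the replicate number as a block, DESeq2 1.42.0 and limma-voom in place of edgeR, an adjusted p of 0.01, and for the lists an estimated correlation, fry, camera on ranks and each gene kept only in its first list. A limma fit with quality weights per library and a fit on halved counts were added after the data were seen.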

Results

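RNA was sequenced from mouse Th17 cells of 2 genotypes. Th17 cells are CD4 helper T cells defined by the cytokines IL-17A and IL-17F. Naive CD4 T cells from the spleen were activated and held for 72 hours under conditions that drive Th17 differentiation. One genotype was labelled wild type for Chaf1b (WT). The other carried Chaf1b alleles flanked by recombination sites together with a Cre recombinase driven by Il17f (KO). Chaf1b encodes a subunit of chromatin assembly factor 1 (CAF-1), the chaperone that deposits histones H3 and H4 on newly replicated DNA. Each genotype had 3 libraries, described in the labels as biological replicates. The WT libraries held 40402762, 38099488 and 45232055 counts and the KO libraries 35708879, 38395131 and 37139371, with 19944 to 20725 genes counted per library. The 7 ChIP-seq, ATAC-seq and CUT&Tag samples of the series were not analysed here.

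The comparison asked how Chaf1b affects gene expression in Th17 cells, and the targeted gene was read first. Chaf1b itself (ENSMUSG00000022945.13) was not lower in the libraries labelled KO. It was counted at 12.0 ± 0.99 CPM in WT and 14.9 ± 1.38 CPM in KO (mean ± SD, n = 3), from 541, 438 and 525 counts in WT and 572, 567 and 498 in KO. The log2 fold change was 0.31 ± 0.11 (SE), with a 95% interval from 0.07 to 0.55 and an adjusted p of 0.130 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Chaf1a, which encodes the largest CAF-1 subunit, was higher at 71.4 ± 1.46 against 57.3 ± 3.33 CPM (log2 fold change 0.32 ± 0.06, adjusted p = 0.0107 in the same test). The counts sum all exons of a gene and the sources used here do not give the deleted part, so the Chaf1b count cannot check the genotype. The groups are therefore called the libraries labelled KO and WT, and each direction below rests on these labels. The Chaf1b change passed the threshold only when WT replicate 1 was left out (0.38, adjusted p = 0.0138) or in the limma fit with quality weights per library (0.36, adjusted p = 0.0169). The Chaf1a call was lost without WT replicate 2 (adjusted p = 0.0745) or any KO library (0.0554 to 0.0849).

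The libraries labelled KO had far less of the Th17 cytokines and more of the cytotoxic, Th1 and DNA replication genes. Il17a fell 7.39-fold and Il17f 7.09-fold. Ifng rose 2.82-fold, Gzmb 2.61-fold and Prf1 2.56-fold, and 27 of 42 DNA replication genes rose while none fell. Of 14681 genes tested, 938 passed an adjusted p of 0.05, 576 of them higher and 362 lower in the libraries labelled KO, and 178 of these changed at least 2-fold (136 higher, 42 lower). Most changes were modest, with a median absolute log2 fold change of 0.43 among the 938 genes. In all 938 genes every KO library lay on the same side of every WT library. This is no separate evidence, since the test favours such genes. The groups were apart in this way in 26.8% of tested genes, against 10% by chance, with no error set on that share. The number of calls depended on WT replicate 1, which stood apart from the other WT libraries. Without it 2961 genes passed (1589 higher, 1372 lower), while the count was 366 without WT replicate 2 and 295, 314 and 326 without KO replicates 1, 2 and 3, and 244 of the 938 genes passed in all 6 such fits.

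**Figure D1:**
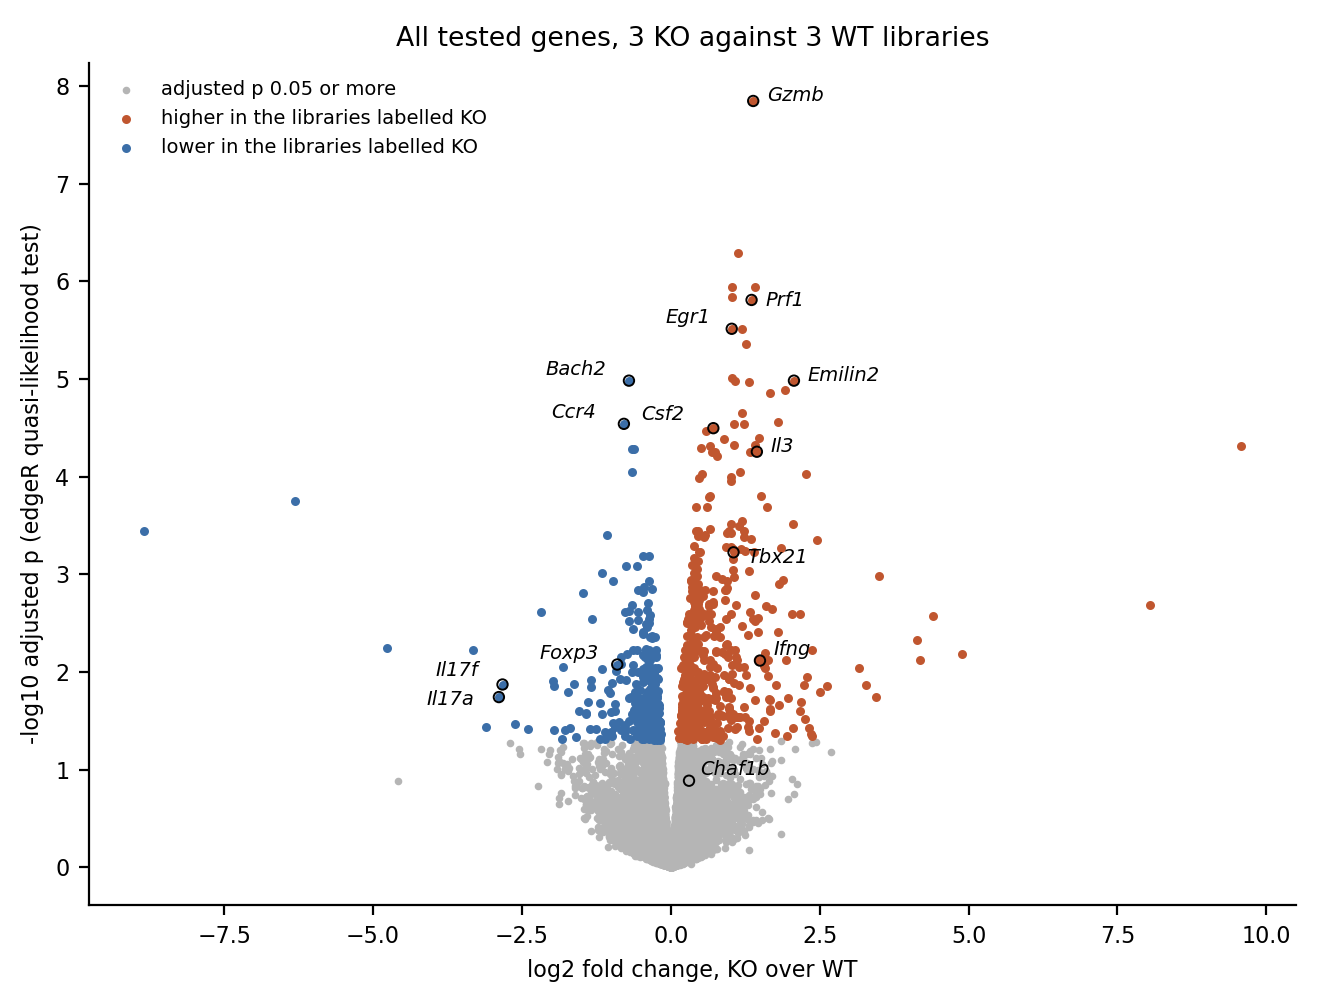
Each of the 14681 tested genes is a point, with the log2 fold change of the libraries labelled KO over WT on the x axis and the negative log10 of the adjusted p of edgeR's quasi-likelihood test on the y axis; orange points are the 576 genes that passed as higher, blue the 362 that passed as lower, grey the rest, and circled genes are named. Gzmb has the smallest adjusted p (1.42e-08), Il17a and Il17f lie far to the left at -2.89 and -2.83, Chaf1b is among the grey points at 0.31, and the points outermost on both sides are genes with almost no counts in 1 group, whose fitted fold change depends on the prior count.

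Genes of the Th17 lineage fell as a group. Il17a was at 66.4 ± 32.7 CPM in WT and 8.98 ± 0.792 CPM in the libraries labelled KO (log2 fold change -2.89 ± 0.39, adjusted p = 0.0181), and Il17f at 41.4 ± 20.8 and 5.83 ± 0.571 CPM (-2.83 ± 0.39, adjusted p = 0.0135; edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment here and for every gene below). Rora, a nuclear receptor gene, fell by 0.42 on the log2 scale, the chemokine gene Ccl20 by 0.41, and the factors Irf4 and Batf, which open Th17 loci early in differentiation, by 0.31 and 0.30. Il1r1, the interleukin 1 receptor, fell by 0.87. Of 23 tested lineage genes 8 were lower and 2 higher (12 lower and 4 higher adjusted over the list alone), the higher pair being Tmem176a (1.59 ± 0.29) and Tmem176b (1.15 ± 0.21), ion channel genes common in Th17 cells. The list passed camera (adjusted p = 1.61e-05). Il21 (-2.08 ± 0.53, adjusted p = 0.0835) and Il23r (-1.52 ± 0.45, adjusted p = 0.0771) had every KO value below every WT value without passing, and Il22, near the detection floor at 0.288 ± 0.0384 and 0.754 ± 0.325 CPM, did not pass either (1.38 ± 0.45, adjusted p = 0.0993). Il10 did not differ detectably (-0.07 ± 0.34, adjusted p = 0.931). The label of the KO samples places Cre under Il17f, so Il17f is also the locus that drives the recombinase, and Il17a is among its near neighbours. The WT label gives only the state of Chaf1b and does not say whether the Cre is present. No library labelled as carrying the Cre alone was analysed here. WT replicate 1 held 104 CPM of Il17a, against 52.4 and 43.1 in WT replicates 2 and 3, and the KO libraries 8.60, 8.44 and 9.89. The Il17a call was lost without KO replicate 1 (adjusted p = 0.0507) or KO replicate 2 (0.0712) and that of Il17f without KO replicate 2 (0.0522) or with no filter on low counts (0.0578), with log2 fold changes still below 0 in each. Il21 passed without WT replicate 1 (log2 fold change -1.34, adjusted p = 6.03e-06) or WT replicate 3 (0.00787), with the stricter filter (0.0228), with DESeq2's Wald test (0.00774) and with quality weights per library (5.69e-04). Il23r passed without WT replicate 3 (0.00861), with no filter (3.96e-05), with DESeq2's Wald test (0.00890) and with quality weights (0.0151). The call of Tmem176a was lost without WT replicate 2 (0.0517) or KO replicate 1 (0.0735). That of Tmem176b was lost without WT replicate 2 (0.0559), KO replicate 2 (0.0621) or KO replicate 3 (0.0674). That of Il1r1 was lost without WT replicate 2 (0.119), KO replicate 1 (0.147) or KO replicate 3 (0.140).

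**Figure D2:**
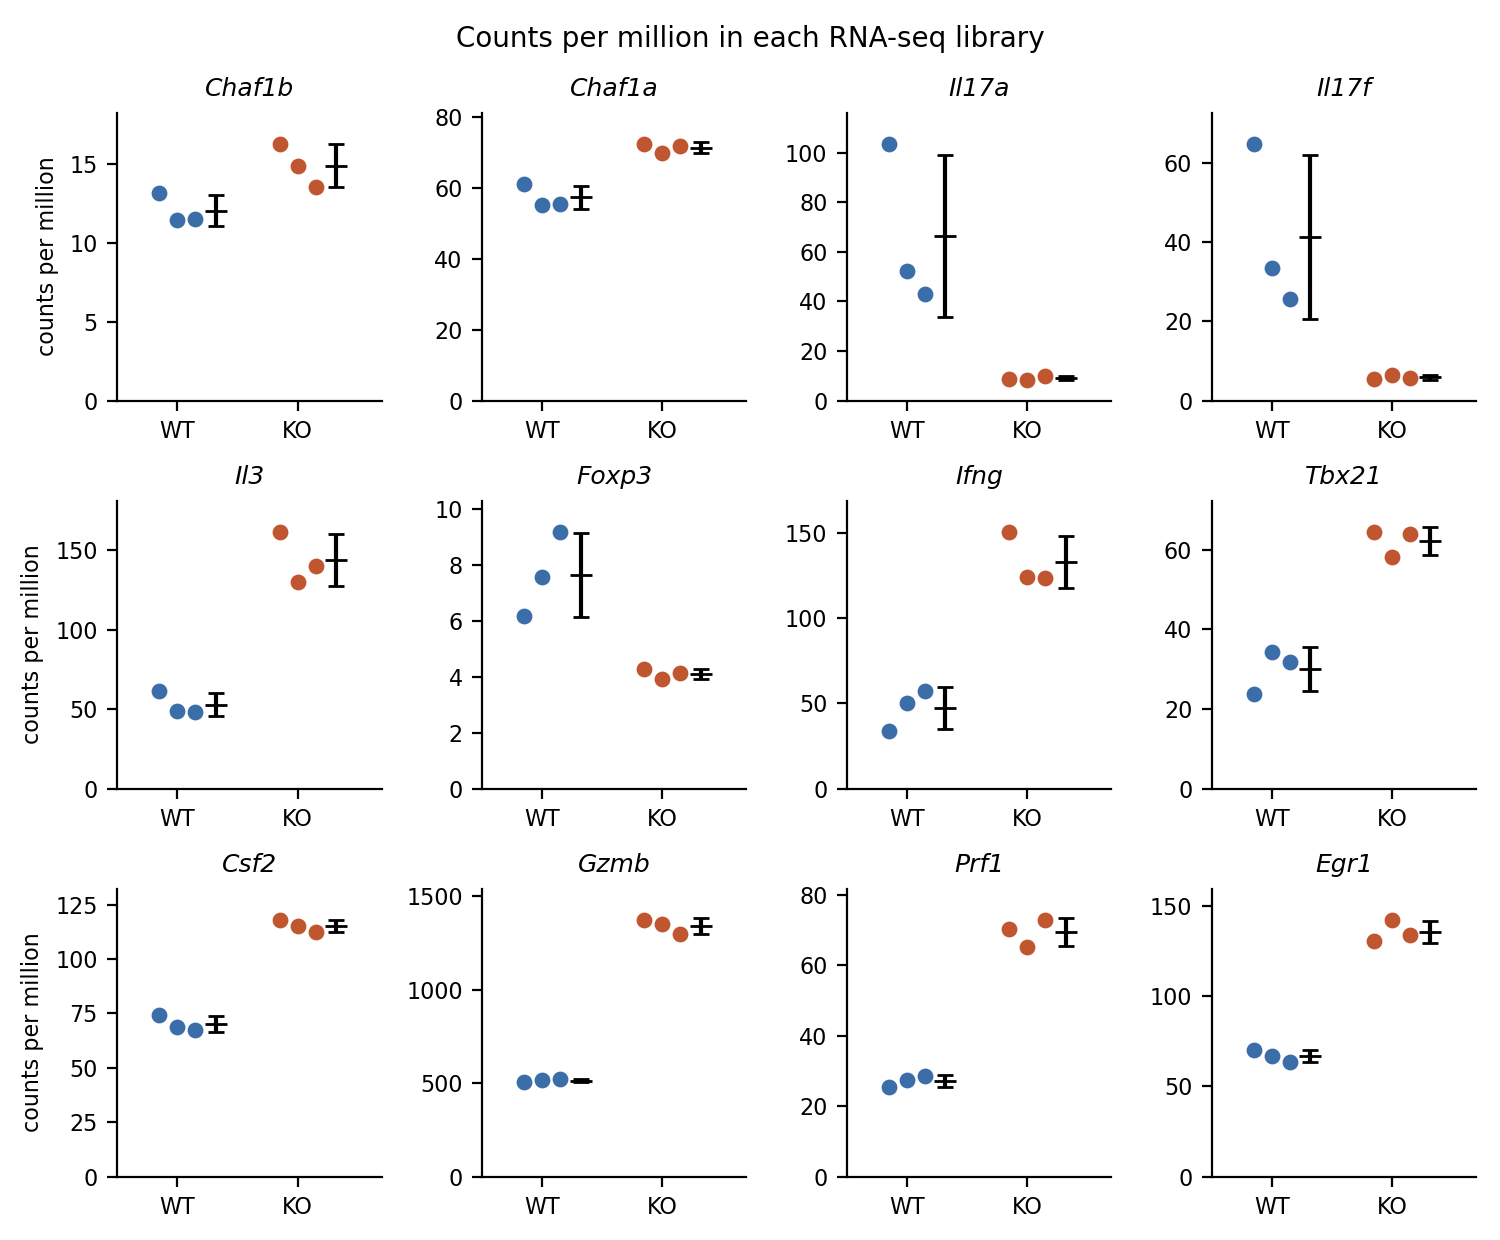
CPM values of 12 genes in each of the 6 RNA-seq libraries, on linear axes from 0; blue points are the 3 WT and orange points the 3 KO libraries, and the bar beside each group gives its mean and SD. Chaf1b is not lower in KO (14.9 against 12.0 CPM), Il17a and Il17f fall to 8.98 and 5.83 CPM with WT replicate 1 above the other WT libraries, and Gzmb rises from 514 to 1341 CPM.

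Cytotoxic and Th1 genes rose. Gzmb, the granule protease granzyme B, went from 514 ± 8.09 to 1341 ± 40.5 CPM (log2 fold change 1.38 ± 0.04, adjusted p = 1.42e-08). The pore-forming perforin gene Prf1 went from 27.1 ± 1.59 to 69.5 ± 3.95 CPM (1.36 ± 0.07, adjusted p = 1.55e-06), and Gzmc (1.41 ± 0.07) and Ctsw (1.40 ± 0.16) rose alike. In the cytotoxic list 10 of 17 tested genes were higher and none lower (12 adjusted over the list alone). Camera gave that list an adjusted p of 7.59e-36, and an adjusted p of 0.0115 with an estimated correlation. The CD8 coreceptor genes in that list did not differ detectably, with 0.08 ± 0.18 for Cd8a and -0.03 ± 0.13 for Cd8b1. Ifng rose from 47.0 ± 12.3 to 133 ± 15.5 CPM (2.82-fold, adjusted p = 0.00766), Tbx21, which encodes the Th1 factor T-bet, from 30.0 ± 5.48 to 62.3 ± 3.46 CPM (1.05 ± 0.12, adjusted p = 5.96e-04), and Il12rb2 and Eomes by 1.05 ± 0.12 and 0.90 ± 0.17. Th1 genes were higher in 7 of 16 cases and lower in none (11 higher and 1 lower adjusted over the list alone; camera adjusted p = 3.01e-12). The call of Ifng was lost with no filter on low counts (adjusted p = 0.0618) and that of Eomes without WT replicate 2 (adjusted p = 0.0559), KO replicate 1 (0.0761) or KO replicate 3 (0.0674).

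Summed markers of 6 other cell types also lay higher in the libraries labelled KO, and those of CD8 T cells and of stromal and endothelial cells did not. The gamma delta T cell constant genes Trdc (0.67 ± 0.10), Tcrg-C1 (1.09 ± 0.19), Tcrg-C2 (1.00 ± 0.09) and Tcrg-C4 (1.05 ± 0.13) were all higher in the libraries labelled KO, and the summed gamma delta markers went from 58.6 ± 5.83 to 97.7 ± 2.16 CPM. These were 4 of the 6 tested members of the list (4 higher and 1 lower adjusted over the list alone). The other members, the transcription factor gene Sox13 (-0.38 ± 0.47) and the kinase gene Blk (-1.85 ± 0.73, the member lower over the list alone), had negative values at low counts and did not pass over all genes (adjusted p = 0.704 and 0.174). The summed NK and innate lymphoid markers went from 234 ± 101 to 450.2 ± 42.6 CPM, almost entirely through Xcl1, a chemokine gene that activated T cells also express (0.98 ± 0.41, adjusted p = 0.275). Eomes and Gzma of that list also belong to the cytotoxic list. Ncr1 and Klrb1c, receptors of NK cells, had no counts in any library, which allows up to 3 counts in each. Summed B cell markers went from 77.8 ± 6.59 to 102 ± 3.92 CPM, with Ighm (0.65 ± 0.09) and Cd79b (0.74 ± 0.19) higher and Ebf1 (-0.66 ± 0.12) lower. Myeloid markers went from 7.31 ± 0.437 to 12.6 ± 0.549 CPM, mainly through Fcer1g (2.46 ± 0.28). Dendritic cell markers went from 167 ± 6.53 to 223 ± 4.38 CPM, mainly through Cd74 (0.52 ± 0.05). Erythroid markers went from 44.4 ± 1.84 to 61.3 ± 1.60 CPM, mainly through Car2 (0.45 ± 0.06), while stromal and endothelial markers went from 32.9 ± 2.22 to 28.6 ± 1.02 CPM. For these 7 sums the KO and WT libraries did not overlap, and the exact permutation test gave p = 0.1 (two-sided), the smallest value that 3 against 3 libraries allow. The summed CD8 T cell markers were at 14.8 ± 1.08 and 14.7 ± 2.13 CPM (exact permutation p = 1) and the CD4 T cell markers at 3426 ± 332 and 3172 ± 37.3 CPM (exact permutation p = 0.2). The CD4 T cell list holds Cd4 with genes such as Cd3e, Lck and Cd5 that CD8 T cells also express. Its sum therefore cannot measure CD4 T cells alone. Of its 12 genes Zap70 (-0.22 ± 0.04) alone passed over all genes (2 higher and 4 lower adjusted over the list alone). Fitted values were negative for 7 and positive for 5. Cd4 itself was at 293 CPM of the library total in WT and 223 in the libraries labelled KO. It had 14035, 10339 and 11778 counts in WT and 7606, 8974 and 8243 in KO, and did not pass over all genes.

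Genes published as higher in pathogenic (encephalitogenic) Th17 cells were shifted upward as a list in the libraries labelled KO, with 8 of 19 past the threshold as higher. Csf2, which encodes the cytokine GM-CSF, rose from 70.2 ± 3.65 to 115 ± 2.88 CPM (log2 fold change 0.71 ± 0.06, adjusted p = 3.19e-05) and the related cytokine gene Il3 from 52.9 ± 7.44 to 144 ± 16.3 CPM (1.45 ± 0.11, adjusted p = 5.56e-05). Gzmb and Tbx21 were also among the 8, and 1 gene, Il1r1, was lower (11 and 3 adjusted over the list alone; camera adjusted p = 1.42e-16). Il23r, Il22 and Bhlhe40 of the same list did not pass. In the wider list of cytokines and chemokines 8 of 30 were higher and 3 lower (16 and 6 adjusted over the list alone; camera adjusted p = 8.21e-09, higher on balance). There the interferon gamma, Il3, Il13, lymphotoxin and Tnf genes rose while Il17a, Il17f and Ccl20 fell. These lists share members, so their tests are not independent of each other or of the Th1 and Th17 lists.

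Genes of DNA replication were shifted upward as a list by a small amount. The cyclin gene Ccne1 (0.55 ± 0.09), E2f1, a factor that drives entry into S phase (0.54 ± 0.11), Tyms (0.52 ± 0.07) and the helicase subunit Gins2 (0.48 ± 0.11) led 27 of 42 genes that were higher, with none lower (33 adjusted over the list alone). The median of the list was 0.31 and all 42 fitted values were above 0. Camera gave an adjusted p of 9.20e-27, and an adjusted p of 0.0115 with an estimated correlation. Histone chaperone genes showed 6 of 21 higher and none lower (9 higher and 1 lower adjusted over the list alone), namely Asf1b (0.50 ± 0.07), Mcm2 (0.39 ± 0.05), Chaf1a, Pcna (0.29 ± 0.07), Nasp and Dnajc9. Mcm2 and Pcna are replication fork genes, and all 6 serve in S phase. Camera gave that list an adjusted p of 0.00174, and an adjusted p of 0.0710 with an estimated correlation. None of the 33 genes of G2 and mitosis passed (camera adjusted p = 0.147), and none of the 23 replication-dependent histone genes did (0.0902), although 3 of the latter were higher and 1 lower adjusted over the list alone. The G2 list passed without WT replicate 3 (0.0204) and on ranks (0.0294), and the histone list without KO replicate 3 (0.0248), with fry (0.0439) and on ranks (0.0294). Gins2, Pcna and E2f1 lost their calls in at least 2 of the 6 fits without a library (adjusted p up to 0.143, 0.181 and 0.0968, the first without KO replicate 3 and the others without KO replicate 1). Pcna also lost its call with the replicate number as a block (0.0553).

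Genes of TGF-beta signalling, one of the signals that induce Th17 and regulatory T cells, fell as a group. Ldlrad4 (-1.34 ± 0.27), Pmepa1 (-0.56 ± 0.12), Smad3 (-0.46 ± 0.11), Ski (-0.40 ± 0.06) and Skil (-0.34 ± 0.06) were the 5 of 15 tested genes that were lower, and 1 was higher (9 lower and 2 higher adjusted over the list alone; camera adjusted p = 1.76e-04). Smad3 transmits the TGF-beta signal, whereas Ldlrad4, Pmepa1, Ski and Skil restrain it. Foxp3, which defines regulatory T cells, fell from 7.66 ± 1.51 to 4.11 ± 0.171 CPM (-0.90 ± 0.16, adjusted p = 0.00841). The regulatory T cell list as a whole did not pass (camera adjusted p = 0.429), with Nt5e lower (-0.71 ± 0.16) and Ikzf2 (0.61 ± 0.13) and Capg (0.24 ± 0.06) higher out of 17 (3 lower and 3 higher adjusted over the list alone). Bach2, a repressor of effector differentiation, fell from 217 ± 5.04 to 133 ± 3.48 CPM (-0.70 ± 0.05, adjusted p = 1.04e-05) and Foxo1 by 0.45 on the log2 scale, the 2 of 15 naive and memory T cell genes that passed (3 lower and 1 higher adjusted over the list alone). That list passed camera (adjusted p = 0.00113), with an adjusted p of 0.377 with an estimated correlation, 0.134 with fry and 0.0983 without WT replicate 1. The Foxp3 call was lost without any 1 of the KO libraries (adjusted p from 0.0533 to 0.0593), and those of Ldlrad4, Pmepa1 and Smad3 were lost in 4 of the 6 fits without a library (adjusted p up to 0.0800, 0.114 and 0.146). Those of Nt5e and Ikzf2 were lost without WT replicate 2 or any KO library (up to 0.142 and 0.127), and that of Nt5e also with limma-voom (0.0512). The log2 fold change of Nt5e was -0.47 without WT replicate 1. That of Capg was lost in every such fit but the fit without WT replicate 1 (up to 0.205), with upper-quartile factors (0.0563) and with the stricter filter (0.0558).

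Genes induced early after T cell receptor stimulation were shifted upward as a list in the libraries labelled KO, with 7 of 20 past the threshold as higher. Egr1 rose from 66.9 ± 3.48 to 136 ± 6.11 CPM (log2 fold change 1.02 ± 0.06, adjusted p = 3.06e-06), and Egr3 (1.18 ± 0.13), Fosb (0.95 ± 0.10) and Fos (0.88 ± 0.22) rose as well. In the same list 2 genes, Irf4 and Myc, were lower (9 higher and 3 lower adjusted over the list alone; camera adjusted p = 5.35e-09). Among 15 inhibitory receptor and exhaustion genes 7 were higher and 2, Btla and Cd200, lower (8 and 2 adjusted over the list alone), led by Cd244a (2.06 ± 0.22, at 0.856 ± 0.142 and 3.59 ± 0.165 CPM), Cd160 (1.02 ± 0.23), Havcr2, which encodes TIM-3 (0.91 ± 0.12), and Ikzf2. This list had a camera adjusted p of 2.48e-05, and an adjusted p of 0.0798 with an estimated correlation. The calls of Fos and Cd160 were lost in 5 and 4 of the 6 fits without a library (adjusted p up to 0.160 and 0.131), and that of Fos also with upper-quartile factors (0.0531).

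Lists of antigen presentation, glycolysis, cholesterol synthesis, the unfolded protein and stress response and oxidative phosphorylation passed camera as higher. Of these lists cholesterol synthesis alone still passed with an estimated correlation (adjusted p = 0.0382). Their median log2 fold changes were, in that order, 0.35, 0.17, 0.19, 0.08 and 0.08. The housekeeping control list had a median of 0.17, with all 11 fitted values above 0. Whether these lists rose beyond the housekeeping genes was not tested. The MHC class I genes H2-Q7 (1.16 ± 0.11), H2-Q6 (0.97 ± 0.22) and H2-Q4 (0.67 ± 0.06) and the class I light chain gene B2m (0.50 ± 0.04) led 8 of 15 antigen presentation genes that were higher, with none lower (9 higher and 1 lower adjusted over the list alone; camera adjusted p = 5.82e-12, and adjusted p = 0.0798 with an estimated correlation). The H2-Q genes are near-identical copies, and reads that fit several places were not counted, so the share of each copy is uncertain. In glycolysis 7 of 21 genes were higher and none lower (9 adjusted over the list alone), among them the glucose transporter gene Slc2a3 (0.75 ± 0.06), Eno1 (0.39 ± 0.08), Pgam1 (0.37 ± 0.06) and Gpi1 (0.34 ± 0.05; camera adjusted p = 2.95e-07, and adjusted p = 0.305 with an estimated correlation). Cholesterol synthesis showed 4 of 24 higher and none lower (12 adjusted over the list alone; camera adjusted p = 6.49e-05), among them Cyp51 (0.33 ± 0.06) and Stard4 (0.29 ± 0.07). The endoplasmic reticulum chaperones Sdf2l1 (0.42 ± 0.04), Pdia4 (0.28 ± 0.04) and Hspa5 (0.27 ± 0.05) were the 3 of 21 unfolded protein and stress response genes that passed (5 adjusted over the list alone; camera adjusted p = 0.00168, and adjusted p = 0.377 with an estimated correlation). No gene of oxidative phosphorylation passed singly, with Atp5b at 0.13 ± 0.04, Atp5a1 at 0.13 ± 0.04 and Cox4i1 at 0.07 ± 0.05, although camera gave the 27 genes an adjusted p of 0.0327 (adjusted p = 0.394 with an estimated correlation, 0.160 without KO replicate 1, 0.0676 without WT replicate 2 and 0.0529 with fry). Atp5b (5.89e-04), Atp5a1 (0.00320) and Cox4i1 (0.12, adjusted p = 0.0383) passed without WT replicate 1, and Atp5b (0.00287) and Atp5a1 (0.0113) also with quality weights per library. The calls of H2-Q6, Eno1 and Stard4 were each lost in 4 of the 6 fits without a library, that of Cyp51 in 3 and that of Hspa5 in 2, with adjusted p up to 0.207. Stard4 also lost its call with the replicate number as a block (0.0633).

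**Figure D3:**
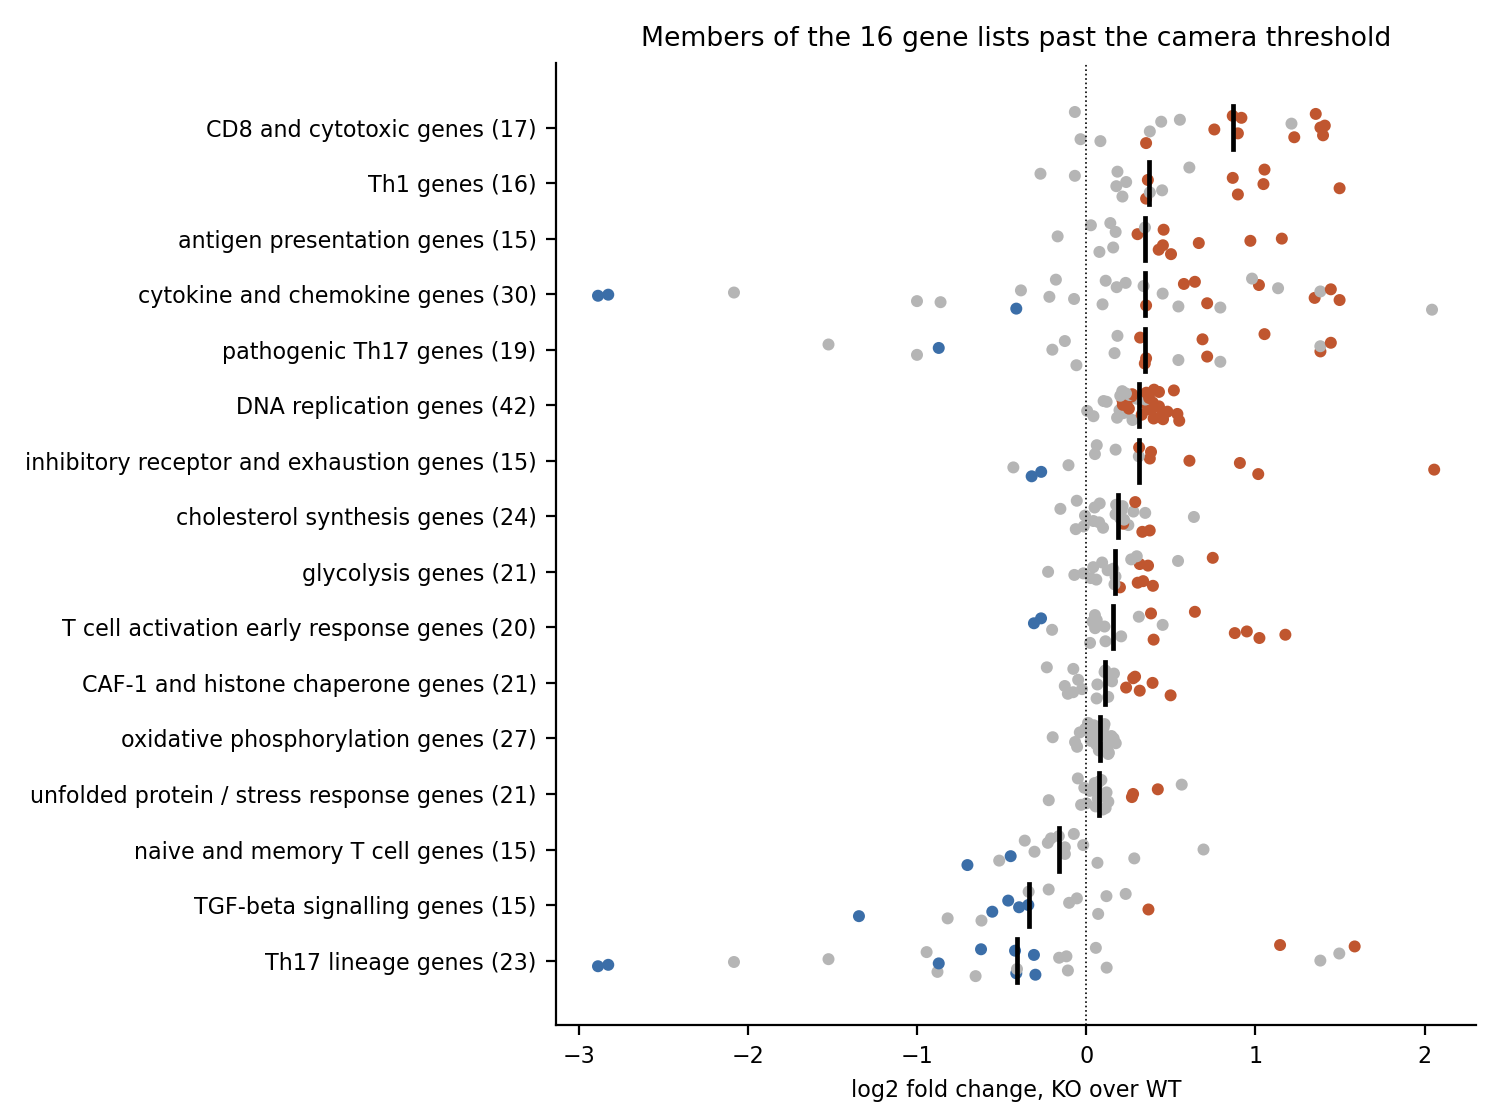
Members of the 16 gene lists past the camera threshold, 1 row per list with the number of tested genes in brackets; each point is a gene placed at its log2 fold change (libraries labelled KO over WT), orange or blue where it passed as higher or lower and grey where it did not, and the black bar is the median of the list. Medians range from -0.41 for the Th17 lineage to 0.87 for the cytotoxic genes, and the 42 DNA replication genes sit closely around 0.31.

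In all, 16 of 29 tested lists passed camera with its preset correlation of 0.01, 13 higher and 3 lower in the libraries labelled KO. With an estimated correlation 9 still passed camera, at adjusted p far larger than with the preset. These were the cytotoxic (0.0115), DNA replication (0.0115), pathogenic Th17 (0.0160), Th1 (0.0142), early response (0.0154), cytokine and chemokine (0.0154), Th17 lineage (0.0382), cholesterol (0.0382) and TGF-beta (0.0429) lists. Camera at the preset also called from 2 to 16 lists in every other split of the 6 libraries into 3 and 3. Between the labelled groups, the lists that did not pass camera were often mixed. Among Th2 genes Il13 (1.35 ± 0.15) and the interleukin 33 receptor gene Il1rl1 (0.89 ± 0.18) were higher and the chemokine receptor genes Ccr4 (-0.79 ± 0.06) and Ccr8 (-0.63 ± 0.11) lower, out of 10 (4 higher and 2 lower adjusted over the list alone; median -0.05, mean 0.19, camera adjusted p = 0.959). The Il1rl1 call was lost without WT replicate 2 (0.0536), KO replicate 1 (0.0861) or KO replicate 3 (0.0891). Among 20 chemokine receptor and migration genes 2 were higher, Cxcr6 (0.72 ± 0.12) among them, and 2, Ccr4 and Ccr8, lower (3 and 5 adjusted over the list alone; median 0.07, mean -0.05, camera adjusted p = 0.605 on the lower side). With each gene kept only in its first list, which left 11 of the 20, this list turned and passed as higher (0.00734). None of 8 non-pathogenic Th17 genes passed (2 lower adjusted over the list alone; camera adjusted p = 0.0686). Their list passed as lower in 5 alternatives, namely without WT replicate 1 (0.00358) or KO replicate 1 (0.0286), with the block (0.0437), with no filter (0.0258) and on ranks (0.0478). Of 11 follicular helper genes 2, Btla and Cd200, were lower (4 adjusted over the list alone; 0.0617). This list passed as lower in 9 alternatives, namely without WT replicate 1 (0.0137), 2 (0.0481) or 3 (0.0432) or KO replicate 3 (0.0298), with the block (0.0366), no filter (0.0258), the stricter filter (0.0110), halved counts (0.0370) and fry (0.0259). The methyltransferase genes Setd1b (-0.27 ± 0.06), Kmt2c (-0.26 ± 0.06), Kmt2d (-0.22 ± 0.05) and Kmt2a (-0.20 ± 0.05) were lower among 17 genes that write or erase H3K4 methylation (5 adjusted over the list alone; camera adjusted p = 0.0617), but each lost its call in 3 or 4 of the 6 fits without a library and with the replicate number as a block. Their list passed without WT replicate 1 (0.0365) or KO replicate 3 (0.0298), with no filter (0.0264) and with fry (0.0359).

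Of 30 p53 target genes Plk2 (0.43) and Perp (0.21) were higher and Trp53inp1 (-0.47) and Phlda3 (-0.24) lower (2 and 2 adjusted over the list alone; camera adjusted p = 0.524). The calls of Perp and Phlda3 were lost without WT replicate 2 or any KO library (adjusted p up to 0.163 and 0.197) and with the replicate number as a block (0.0708 and 0.0945). Phlda3 also lost its call with upper-quartile factors (0.0536) and limma-voom (0.0610). Of 19 apoptosis regulators Bcl2l11, which encodes the death inducer BIM, was lower (-0.63 ± 0.10) and 1 gene was higher (1 and 1 adjusted over the list alone; camera adjusted p = 0.471). Isg20 (1.02 ± 0.11) was the only 1 of 28 interferon-stimulated genes past the threshold (1 adjusted over the list alone; 0.0591). That list passed as higher in 6 alternatives, namely without WT replicate 1 (0.0339), KO replicate 2 (0.0199) or KO replicate 3 (0.0312), with the block (0.0363), with no filter (0.00243) and with each gene kept in 1 list (0.0163). P4ha1 (0.44) and Ero1l (0.34) were the 2 of 16 hypoxia genes that passed (3 adjusted over the list alone; 0.148). Their list passed without WT replicate 1 (0.0362). Among 17 heterochromatin genes Ehmt2 was lower (-0.24; 2 lower adjusted over the list alone; median 0.01, mean -0.03, camera adjusted p = 0.471 on the lower side). Of 18 germline genes 2 were tested and Slc25a31 was lower. Among sex-linked genes Xist, the X inactivation transcript, was lower (-0.46 ± 0.08, adjusted p = 0.0114). The Y-linked genes Kdm5d, Eif2s3y and Ddx3y had no counts in any library, and Uty had 1 count, in WT replicate 1. The sex-linked sum given below is therefore almost wholly Xist, and these genes give no sign of a sex difference between the groups. Of 11 housekeeping genes 5 were higher and none lower (7 adjusted over the list alone), B2m, Actb, Hprt, Ywhaz and Gapdh, and their sum went from 8580 ± 335 to 9298 ± 124 CPM. The exact permutation test gave p = 0.1 for that sum and for the sex-linked sum (651 ± 45.3 to 464 ± 56.1 CPM), p = 1 for mitochondrially encoded genes (1159 ± 179 and 1173 ± 62.4 CPM) and p = 0.6 for ribosomal protein genes (93408 ± 2069 and 92543 ± 1164 CPM).

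Among genes past the threshold at 5 CPM or more, the largest rises were in Emilin2, an extracellular matrix gene (4.82 ± 0.778 to 20.2 ± 2.02 CPM, log2 fold change 2.07 ± 0.14, adjusted p = 1.04e-05), Avil (1.91 ± 0.13) and the cytokine gene Il6 (1.80 ± 0.14, from 3.24 ± 0.367 to 11.3 ± 0.735 CPM). Asb2 (1.67 ± 0.12), Plac8 (1.62 ± 0.16), Tm6sf1 (1.52 ± 0.15), Ifng, Gpr141 (1.48 ± 0.12), Il3 and Gzmc completed the 10 largest rises. The largest falls after Il17a and Il17f were in the proton pump subunit gene Atp6v0d2 (-1.19 ± 0.24, adjusted p = 0.0210), the growth factor gene Fgf2 (-1.16 ± 0.15, adjusted p = 9.80e-04) and the gap junction gene Gja1 (-1.07 ± 0.12, adjusted p = 3.99e-04). Ramp1 (-0.99 ± 0.19), Fam160a1 (-0.97 ± 0.13), Zfp831 (-0.92 ± 0.17), Foxp3 and Angptl2 (-0.85 ± 0.17) followed. All 10 rises kept their call in every fit without a library. Among the falls Fgf2, Gja1 and Fam160a1 did so, and Atp6v0d2, Ramp1, Zfp831 and Angptl2 did not, with adjusted p up to 0.0842, 0.0844, 0.0719 and 0.0588.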

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

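The fits with quality weights per library and with halved counts were chosen after the data were seen. The count of 938 genes stayed within 1.5 times of its value with DESeq2 size factors (943), upper-quartile factors (936), the stricter filter (821), limma-voom (864), the DESeq2 Wald test (1325), halved counts (938, of which 905 shared) and the replicate number as a block (671, of which 633 shared), although the numbers did not pair the libraries (residual correlations of -0.040, -0.028 and 8.74e-04). It moved to 1568 with no filter, 339 at an adjusted p of 0.01 and 2862 with quality weights, and ranged from 295 (without KO replicate 1) to 2961 (without WT replicate 1). The count at 2-fold or more, 178, moved to 70 with the stricter filter, which tests fewer genes, to 102 at an adjusted p of 0.01 and to 387 with quality weights, and ranged from 103 (without KO replicate 2) to 315 (without WT replicate 1). The Chaf1b log2 fold change of 0.31 ranged from 0.23 to 0.38 over the fits without a library and passed without WT replicate 1 (0.38) and with quality weights (0.36), with adjusted p from 0.0138 to 0.422 over all alternatives. The 16 gene lists became 9 with an estimated correlation. Of 84 genes past the threshold that the naming rule picked, 45 kept their call in all alternatives run on them. Outside the fits without a library, calls were lost with no filter (Il17f and Ifng), the block (Pcna, Stard4, Perp, Phlda3, Setd1b, Kmt2a, Kmt2c and Kmt2d), upper-quartile factors (Capg, Fos, Kmt2a and Phlda3), limma-voom (Nt5e, Kmt2a and Phlda3) and the stricter filter (Capg). Il10 was at -0.07 and turned to 0.27 without WT replicate 3, 0.06 without KO replicate 3 and 0.28 with quality weights (range without a library -0.32 to 0.27). Lists that did not pass turned direction as follows, as adjusted p: Th2 with the block (0.723), no filter (0.745), fry (0.966), ranks (0.756) and without WT replicate 1 or any KO library (range without a library 0.492 to 0.997); regulatory T cell without WT replicate 1 (0.575, range 0.164 to 0.594); chemokine receptor without WT replicate 1 (0.489, range 0.276 to 0.898), on ranks (0.822) and with each gene kept in 1 list (0.00734, past the threshold as higher), which removes genes of earlier lists. The cause of the other changes was not tested. Genes of low level, such as Il22 and Il23r, had no value under the stricter filter. Depth limited genes under 1 CPM, where the median half-width of the 95% interval was 1.06 on the log2 scale.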

Other observations

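The tests on Chaf1b, the test on CD8 T cells and that on the chromosomes below were chosen after the result was seen, as were the separate pools of receptor genes, the pools without a library and the bound they are held to, the shares per locus, the places of the genes counted in 1 genotype, the genes named in the next paragraph and those named as counted in 1 genotype alone.

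Some genes outside the fixed lists were also higher. Serpinb6b went from 232 ± 3.00 to 507 ± 26.0 CPM (log2 fold change 1.13 ± 0.05, adjusted p = 5.13e-07 in edgeR's quasi-likelihood test) and Serpinb9, whose product blocks granzyme B inside the cell, from 135 ± 11.8 to 287 ± 19.8 CPM (1.09 ± 0.07, adjusted p = 1.04e-05). Il23a, a subunit of interleukin 23, went from 128 ± 1.44 to 261 ± 12.4 CPM (1.03 ± 0.05, adjusted p = 1.15e-06), and Il1a (1.26 ± 0.08) and the secreted protein gene Spp1 (1.14 ± 0.11) rose as well.

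Of the 10 splits of the 6 libraries into 3 and 3, only the real one gave 938 genes (highest other 1). Likewise it alone gave 178 genes at 2-fold or more (highest other 1). As many gene lists as in the real split (16) were called in 2 splits, the real one included. Every other split also called lists, from 2 to 16, with at most 1 gene past the threshold. The other split with 16 lists set WT replicate 1 with KO replicates 1 and 2, and no gene passed in it. The splits are too few for a share under 0.05.

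Chaf1b counts were not lower in the libraries labelled KO. Every library correlated better within its label than across, by at least 0.00126, which argues against an exchange of 1 library of each label. Of 42 DNA replication genes 21 had a lower log2 fold change than Chaf1b, so its change lay within their spread. That would be seen with a deleted part too small for a whole-gene count to show. It would be seen equally if the Cre, driven by Il17f, had acted in few of the cells. The count cannot tell these apart. Counts per exon were not analysed here, so whether Chaf1b was lost stays open.

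Cytotoxic genes were higher in the libraries labelled KO, with a median log2 fold change of 1.07 over the 10 that passed, in cultures begun from isolated naive CD4 T cells, an isolation that should leave out CD8, NK and gamma delta T cells and whose purity is not given in the sources used here. More CD8 T cells would raise Cd8a and Cd8b1 alike, and the higher of their upper 95% bounds was 0.49 (0.68 at most without a library, the fit without WT replicate 2), which argues against them. Pooled counts of 6 NK genes, of which 3 were counted, gave -1.10 (95% interval -2.30 to 0.09). Without WT replicate 1, which held 55 counts against 10 to 22 in the others, they gave -0.33 (-1.51 to 0.84). Both upper bounds lay below 1.07, which argues against a rise of that size in these genes. The stricter limit set before the data were seen held with all libraries. It did not hold without WT replicate 1, KO replicate 2 (upper bound 0.48) or KO replicate 3 (0.46). At so few counts a smaller rise of NK cells stays open. Pooled gamma and delta variable genes gave 0.43 ± 0.07 (upper 95% bound 0.590), a pool that includes 10 alpha genes shared with delta (0.09 ± 0.09). Delta genes alone gave 0.61 ± 0.14 (upper bound 0.903) and gamma genes 0.87 ± 0.12 (upper bound 1.122). Only the gamma bound lay above 1.07. The whole pool still exceeded the stricter limit set for it before the data were seen. Gamma delta T cells left over from the isolation therefore stay open. A change within the CD4 T cells themselves stays open as well and was not tested.

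Some genes were counted in 1 genotype alone, at most 3 counts in every library of one label and at least 10 in every library of the other, 10 genes in the real split and at most 2 in the others, which are too few for a share under 0.05. Glrp1, at 0 in all WT libraries, was at least 32.9-fold higher in the libraries labelled KO, and Slc15a2, at 0 in all KO libraries, at least 18.4-fold lower, against a floor of 3 counts per library. A passenger chromosome segment around the engineered loci could carry such differences: 7.59% of the 79 tested neighbours of Chaf1b and Il17f passed, 5 of 40 (12.5%) at Il17f (Msc, Trpa1, Il17a, Mcm3 and Prim2, of which Il17a is in the Th17 list and Mcm3 and Prim2 are in the DNA replication list) and 1 of 39 (2.56%) at Chaf1b, against 6.39% of all genes. Of the 10 genes 8 could be placed, and 5 of these (Capn11, Fam83c, Fmr1nb, Samd3 and Slc25a31) lie on chromosomes with neither locus, which argues against a segment around the loci as the whole cause. The other 3 lie outside the neighbours, Slc15a2 157 tested genes from Chaf1b and Slc23a3 and Glrp1 220 and 297 from Il17f, and for these a longer segment cannot be told apart from an effect of the genotype, while a strain difference was not tested for any of them.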
